A study of Homo sapiens with 4 samples.

How the data were processed

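RNA from HepG2 and K562 cells with a stable ADAR knockdown or a scrambled control was sequenced on an Illumina GAIIx as paired ends of 76 bases, per the labels. Each of the 4 groups had 1 sample with 2 technical replicates, per the labels, and groups were taken from the labels. TopHat, SAMtools and the hg19 build are named in the submitters' processing notes, without versions. The counting tool, the gene annotation, the use of strand and any scaling for depth are not given in the sources used here.

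Each cell line had 1 deposited table, which listed genes by Ensembl identifier with a symbol where one was given. Per the file headers, each row held an average for the knockdown and an average for the control, treated here as a signal, since the authors' unit is not named. The averages were whole numbers divided by a divisor that differed between genes: 98.8% of the HepG2 rows and 99.7% of the K562 rows gave whole numbers in both columns at a common multiplier of up to 40, within a tolerance of 1e-06. What the averages were taken over is not stated. The deposited log2 fold equalled the log2 of the ratio of the averages after adding 1, and the deposited signed fold, treated as a score because it is negative where the knockdown is lower, equalled the same ratio. Both tables held only rows at or past 2-fold. The authors' selection gave no p-values, and the averages were the authors' own, so no SD, n or test was attached. The library depth is unknown, and the precision of low averages with it.

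Folds were recomputed from the deposited averages with the same pseudocount of 1, which understates the difference of low genes. Duplicate symbols given in a table were reduced to the row with the highest mean average, which left 1409 of 1413 rows in HepG2 and 942 of 945 in K562. Of the rows, 463 in HepG2 and 496 in K562 had no symbol; they were kept under their identifier. Gene types, names and overlaps came from GENCODE release 29 on GRCh38 by Ensembl identifier, which matched 1278 of 1413 and 840 of 945 identifiers. Because the files used hg19, no coordinates are printed. Antisense, overlapping and near-identical genes are treated as uncertain. The HepG2 table held 49 overlapping pairs of listed genes, 34 on opposite strands, and the K562 table held 20, of which 11 were on opposite strands. In 47 of the HepG2 pairs and 16 of the K562 pairs, both genes went in the same direction. Whether such pairs shared reads was not tested, so their genes may not be separate observations.

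With 1 sample per group, tables were described and not tested. Before the data were examined, 32 gene lists were fixed, 23 by name and 9 by symbol pattern. For a list with 5 or more listed members, the median log2 fold was placed among 10000 random sets of the same size from the same table, drawn within 5 bins of mean average. These percentiles describe the listed genes of these libraries and are not p-values. Tested on simulated lists in the HepG2 table of 1409 genes, 6% of 100 random lists fell outside the central 95%, and 46% of 50 lists of 20 genes with 16 higher were placed above it; in the K562 table of 942 genes the shares were 3% and 98%. Genes in both tables were matched by symbol, or by identifier where no symbol was given, and their same-direction share was set against 10000 shuffles of directions within each table.

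The rule for named genes, also fixed before the data were examined, took ADAR, the 10 highest and 10 lowest log2 folds among symbols whose larger average was at or above the table's median, up to 4 members of each list with 3 or more listed members by size of fold, members of lists with 1 or 2, and up to 8 shared symbols in each combination of directions. Symbol patterns also take pseudogenes and related names. Some genes that the rule takes are not reported here. Alternatives were thresholds of 3-fold and 4-fold, a larger average at or above the lower quartile or at or above 10, pseudocounts of 1 and 0.1, every row as deposited, matching by identifier, and random sets not matched on expression. Protein-coding genes alone, rows with a symbol alone, knockdown averages multiplied or divided by 1.5, and pattern lists without members of another kind were added after seeing the data. A stricter p or q threshold and each technical replicate alone could not be run on these tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.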

Results

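ADAR, the enzyme that converts adenosine to inosine in double-stranded RNA, was knocked down in 2 human cell lines, and RNA was sequenced from the knockdown and from a scrambled control of each line. HepG2 is a line from a hepatocellular carcinoma and K562 is an erythroleukemia line. Cells had been stably transfected with plasmids carrying an siRNA against ADAR or a scrambled sequence. The stated question of the study was how ADAR affects alternative splicing across the genome; the tables used here hold gene-level values, so the comparisons are of gene levels and not of isoforms. There were 4 groups with 1 sample each, and the labels give 2 technical replicates per sample, read as paired ends of 76 bases. Values per technical replicate were not used here, so no difference below has a replicate check, no error can be attached to it, and no p-value is given. The depth of the libraries is unknown, because each table holds only genes that passed a 2-fold difference.

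The authors' deposited table for HepG2 had 1413 rows for 1409 distinct genes, and the one for K562 had 945 rows for 942. Each row gave the authors' average in the knockdown and in the control. Folds below are the ratio of these averages after adding 1 to each, which matches the deposited folds. Why a gene is not listed cannot be read from the tables: it may have differed by less than 2-fold, lain under a floor, been left out by another filter or not been annotated. The smallest value of the larger average was 14.0 in HepG2 and 13.8 in K562.

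ADAR itself (ENSG00000160710) was lower in the knockdown of both cell lines. In the authors' deposited table for HepG2 its average was 129 in the knockdown against 461 in the control, which was 3.54-fold lower and left 28.1% of the control value. In K562 the average was 131 against 275, which was 2.09-fold lower and left 47.6%. The direction matched the labels in both lines, and the remaining share was larger in K562. Of the 634 genes lower in HepG2, 155 had a lower log2 fold than ADAR. In K562 this held for 506 of the 582 lower genes, so ADAR fell less there than most genes listed as lower.

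In HepG2 several of the genes that stood highest in the knockdown encode inflammatory cytokines or stress-response proteins. Among symbols with a larger average at or above the table's median, the 10 highest folds belonged to LOC541472, IL8, IL1B, IL6, CXCL2, CHAC1, IL1A, INHBE, STC2 and FAM167A. IL8 (ENSG00000169429), a neutrophil chemoattractant, averaged 304 in the knockdown against 2.75 in the control, an 81.3-fold difference. IL6 (ENSG00000136244) averaged 450.2 against 7.83, a 51.1-fold difference. LOC541472 averaged 409.8 against 2.75; the reference annotation names this locus IL6-AS1 and places it on the strand opposite to IL6 where the genes overlap, and since strand-specific counting is not stated, reads from the pair cannot be told apart. IL1B was listed at 0 in the control and at 58.5 in the knockdown, so no fold is given. IL1A, the other interleukin-1 gene, averaged 80.2 against 3.

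Among the 10 lowest folds in HepG2, over the same symbols at or above the median larger average, were those of C5ORF23, MAMDC2, SLC7A8, MYLK3, HPD, MAGEA1, LAMP3 and COL3A1. HPD (ENSG00000158104), a liver enzyme of tyrosine breakdown, averaged 46.9 in the knockdown against 584 in the control, 12.2-fold lower, and it overlaps another listed gene. SLC7A8, a transporter of neutral amino acids, was 13.2-fold lower. COL3A1, a fibrillar collagen gene, was 9.12-fold lower. In all, 775 genes were higher and 634 were lower in the knockdown, or 55.0% higher. At 4-fold or more, 126 were higher and 115 were lower. If the knockdown averages were scaled by 1.5 in either direction, the listed genes still past 2-fold would be 76.3% or 28.2% higher, so the balance of directions in this table rests on a scaling that cannot be checked.

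Of the 64 genes fixed as inflammatory cytokines, chemokines and NF-kB targets, 22 were listed in HepG2, and 20 of these were higher in the knockdown. Their median log2 fold was 2.74, a 6.68-fold difference, at percentile 100 of 10000 random sets of listed genes matched on mean average. Besides IL8, IL1B and IL6, the chemokine gene CXCL2 averaged 184 against 3. CCL2 (log2 fold -2.30) and IL32 (-1.54) were the 2 lower members, named after their values were seen. Of the 49 genes of the integrated stress response and unfolded protein response, 20 were listed and 19 were higher, with a median log2 fold of 2.20 at percentile 100. CHAC1, which degrades glutathione, averaged 199 against 8.5 and was 21.1-fold higher. STC2, a secreted glycoprotein, averaged 1808 against 93 and was 19.2-fold higher. GDF15, a stress-induced cytokine of the TGF-beta family, was 11-fold higher, and SESN2, a stress-induced regulator of mTORC1, was 7.01-fold higher. ATF5 (log2 fold -1.01) was the 1 lower member, named after its value was seen.

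All 19 listed genes of the 42 immediate early genes were higher in the HepG2 knockdown. Their median log2 fold was 1.66, at percentile 99.98 of the matched random sets. EGR1, a zinc-finger transcription factor induced by growth factors, averaged 1407 against 198 and was 7.08-fold higher. DUSP4, a phosphatase that acts on MAP kinases, was 7.76-fold higher. ATF3 was 6.58-fold and MAFF 5.64-fold higher; both encode basic leucine-zipper transcription factors. In K562 the same 3 lists had 4, 1 and 1 listed members, and each of these was lower in the knockdown. Of the 410 protein-coding genes listed in K562, 290 were lower, so these few members do not stand apart.

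**Figure D1:**
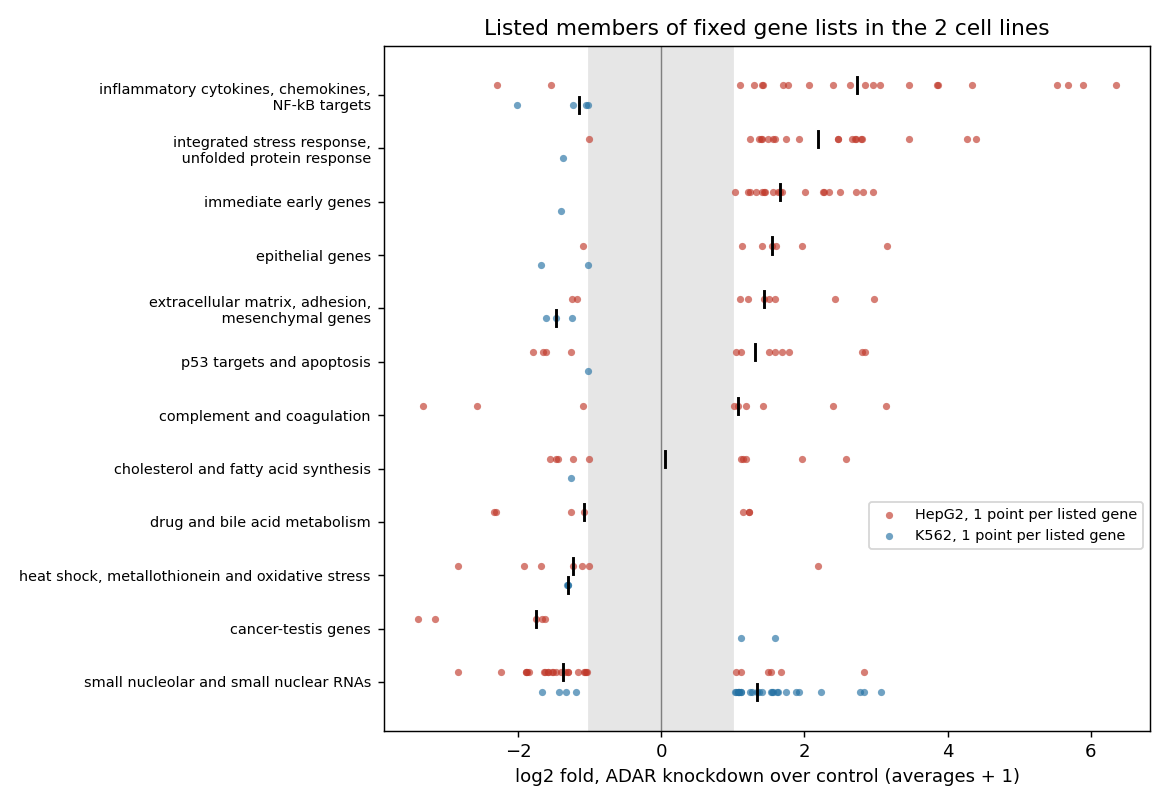
Log2 fold of the ADAR knockdown over the control (x axis, log2 scale, averages plus 1) for listed members of 12 of the fixed gene lists, in HepG2 (red) and K562 (blue). Each point is 1 gene, the black bars are medians of lists with 3 or more listed members, and the grey band is the range under 2-fold that the tables leave out; IL1B in HepG2, at 0 in the control, is drawn at the value that adding 1 gives. The inflammatory, stress-response and immediate early lists lie to the right in HepG2, with medians of 2.74, 2.20 and 1.66. Their few listed K562 members lie to the left, in a table where 290 of 410 protein-coding genes were lower.

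Epithelial, adhesion and cell death genes were also mostly higher in the HepG2 knockdown, by smaller medians. Of 39 epithelial genes, 7 were listed and 6 were higher (median log2 fold 1.54, percentile 96.0). CLDN1, a tight-junction claudin, averaged 1019.9 against 113 and was 8.93-fold higher. The mucin gene MUC1 was 3.92-fold and the keratin gene KRT19 3.05-fold higher. Of 77 extracellular matrix, adhesion and mesenchymal genes, 9 were listed and 7 were higher (median 1.44, percentile 96.1). The integrin genes ITGB8, ITGA2 and ITGB4 were 7.87-fold, 5.39-fold and 3.02-fold higher, and the laminin gene LAMB3 was 2.85-fold higher. Of 49 p53 targets and apoptosis genes, 12 were listed and 8 were higher (median 1.32, percentile 90.3). The members with the largest folds, BIRC3 and SESN2, were already counted in the inflammatory and the stress-response list. BIRC3, an inhibitor of apoptosis and an NF-kB target, was 7.18-fold higher, BBC3, which encodes the proapoptotic protein PUMA, was 3.43-fold higher, and BCL2, which encodes an antiapoptotic protein, was 3.47-fold lower. These 3 medians lay inside the central 95% of the random sets. The epithelial median was at percentile 97.9 when the sets were not matched on expression.

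Genes of the cell cycle went both ways in HepG2. Of 61 such genes, 6 were listed and 4 were higher (median log2 fold 1.12, percentile 54.7). The proto-oncogene MYC averaged 2157 against 848 and was 2.54-fold higher. CDKN2B, an inhibitor of cyclin-dependent kinases, was 2.57-fold higher, CDT1, a replication licensing factor, was 2.28-fold higher, and CCND3, which encodes cyclin D3, averaged 435 against 1089. All 6 listed replication-dependent histone genes were higher (median 1.33, percentile 87.4), with HIST1H2AG at 5.09-fold and HIST1H2AC at 3.02-fold. Histone genes are near-identical copies, and how reads were shared among them is not stated. Of 23 listed symbols of the solute carrier pattern, 11 were higher and 12 were lower (percentile 24.0); without 3 pseudogenes and 1 antisense-named gene, 8 of 19 were higher. SLC7A11, the cystine transporter subunit, was 6.89-fold higher, and SLC6A15, a transporter of neutral amino acids, was 4.86-fold lower.

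Over the lists of liver-related genes, listed members went in both directions in HepG2. Whether liver genes moved together cannot be read from listed genes alone. Of 67 hepatocyte secreted proteins and transcription factors, 4 were listed, and all were higher. IGFBP1, a secreted binding protein of insulin-like growth factors, averaged 97 against 13.2 and was 6.92-fold higher. ONECUT2 was 2.59-fold and FOXA1 2.30-fold higher, and APOE, an apolipoprotein gene, was 2.43-fold higher at a low average of 21.5 against 8.25. Of 58 complement and coagulation genes, 9 were listed, 6 higher and 3 lower (median log2 fold 1.07, inside the central 95% of the random sets). F3, which encodes tissue factor, was 8.84-fold higher and CFB, complement factor B, was 5.29-fold higher, whereas CFHR3 was 5.94-fold lower. CFB overlaps another listed gene. Of 67 genes of cholesterol and fatty acid synthesis, 10 were listed, 5 in each direction. The sterol-pathway enzymes IDI1 and SC4MOL were 2.94-fold and 2.78-fold lower. INSIG1 (log2 fold -1.43), SQLE (-1.22) and ME1 (-1.01), named after their values were seen, were the other lower members. ABCG1, a cholesterol exporter, was 6-fold and ACSL1 3.92-fold higher. The other higher members, also named afterwards, were ANGPTL4, PPARG and ACSL4, so no sterol-pathway enzyme was among the higher ones. Of 79 genes of drug and bile acid metabolism, 7 were listed and 4 were lower (median log2 fold -1.08, percentile 19.1). AKR1C1 was 5.04-fold, AKR1C2 4.96-fold and AKR1C3 2.38-fold lower; these aldo-keto reductases are close paralogs whose reads may not have been separated. CYP1B1, a cytochrome P450 gene that overlaps an antisense gene, was 2.35-fold higher.

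Markers of other cell types were also listed in HepG2. Of 51 erythroid genes, 3 globin genes were listed and were higher in the knockdown: HBM averaged 48.3 against 17.5, HBA2 125 against 47 and HBZ 34.9 against 16.6. HBA2 has a near-identical copy, and HBM and HBZ overlap in the reference annotation. Of 27 fibroblast and endothelial genes, 6 were listed, 3 in each direction. COL3A1 and TAGLN were 9.12-fold and 5.92-fold lower, and COL5A2 and DCN, which encode a fibrillar collagen and the proteoglycan decorin, were 3.82-fold and 2.95-fold higher. DCN averaged 774 against 261, and LUM, named after its values were seen, averaged 1445 against 528. In the HepG2 control, LUM, COL3A1 and DCN averaged 528, 323 and 261. Of liver genes, APOE averaged 8.25 there and HPD 584. Whether averages of different genes can be compared is unknown, since what they were taken over is not stated. That the cells were HepG2 rests on the labels and was not tested. No gene of the myeloid and lymphoid or the megakaryocyte and platelet lists was in the HepG2 table. Of 53 hypoxia and glycolysis genes, 7 were listed and 4 were higher (percentile 37.0). VEGFA, the vascular growth factor, was 2.54-fold higher and the enolase gene ENO3 was 7.27-fold lower.

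The listed cancer-testis genes and most listed heat shock genes were lower in the HepG2 knockdown. Of 38 genes of heat shock, metallothioneins and oxidative stress, 7 were listed and 6 were lower (median log2 fold -1.23, percentile 3.70), which lay inside the central 95% of the random sets. HSPA8, the constitutive HSP70 chaperone, averaged 1166 against 4382 and was 3.75-fold lower. HSPA1A, the inducible form, was 7.17-fold lower and DNAJA1, an HSP40 cochaperone, was 3.21-fold lower. TXNIP, the thioredoxin-interacting protein, was 4.55-fold higher. All 5 genes that the cancer-testis symbol pattern took were lower (median -1.75, percentile 1.31), among them MAGEA1 at 10.5-fold and CTAG2 at 8.93-fold. The median member, MAGED1, 3.36-fold lower, is of the MAGE family but is not a cancer-testis gene. Without it fewer than 5 members remain, too few for a percentile. MAGEA6 was 3.17-fold lower and shares sequence with a paralog in the same list.

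Small nucleolar RNAs were mostly lower in the HepG2 knockdown and mostly higher in the K562 knockdown, and the few small nuclear RNAs listed beside them went both ways. Of the list of both kinds, 28 were listed in HepG2, 22 lower and 6 higher, with a median log2 fold of -1.37 at percentile 0.16 of the matched random sets. SNORD1B averaged 2 against 20.5 and SNORA33 averaged 4 against 22.5, whereas SNORD3A, the U3 RNA of ribosomal RNA processing, averaged 27.5 against 3. In K562, 29 were listed, 25 higher and 4 lower, with a median of 1.33 at percentile 100. SNORA74B averaged 53.5 against 5.5, SNORA13 averaged 31 against 3.5 and SNORA66 averaged 39 against 7.5. The row named SNORA74B carries an identifier that the reference annotation names SNORA74A. These RNAs have low averages, with a median larger average of 31.2 in HepG2 and 27.5 in K562, and members of their families share sequence. The pattern also took 7SL and Y RNAs, and SNORD87 under 2 identifiers in HepG2; without 6 such RNAs in K562 and with SNORD87 once, 21 of 23 were higher in K562 (percentile 100) and 21 of 27 were lower in HepG2 (percentile 0.34). Small nucleolar RNAs alone, a split made after the values were seen, had 21 of 23 lower in HepG2 (percentile 0.03) and 19 of 20 higher in K562. This split counts SNORD87 under both identifiers. Of 4 small nuclear RNAs in HepG2, 3 were higher: the row named RNU4-2 averaged 114 against 40, RNU6-1161P 31 against 9 and RN7SKP70 61.5 against 20.5, whereas RN7SK averaged 12 against 31. In K562 the row named RNU2-2 was higher and RNU2-27P was lower. All of these but RN7SK carry identifiers that the reference annotation gives pseudogene names.

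Few genes of the pathways closest to ADAR were listed. Of 58 interferon-stimulated genes, 3 were listed in HepG2 and were higher: IFI16, a sensor of DNA, was 3.88-fold higher, IFIT2 2.16-fold and PARP9 2.12-fold. In K562, 2 were listed and were lower, UBE2L6 by a factor of 3.34 and IFIT2 by a factor of 2.75. IFIT2 overlaps another gene listed in HepG2. None of the 21 genes of double-stranded RNA sensing was listed in either table. Of 20 editing enzymes only ADAR was listed, in both lines. Of 138 splicing regulators and spliceosome components, SNRPN (2.58-fold) and CLK4 (2.18-fold) were listed and higher in HepG2, and MBNL3 (2.14-fold) was listed and higher in K562. Of 19 antigen presentation genes, HLA-B was 2.03-fold higher in HepG2 and none was listed in K562. These counts describe listed genes and do not show that the other members were unaltered.

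In K562 the balance was toward lower values in the knockdown, and folds were smaller. Of 942 genes, 360 were higher and 582 were lower, or 38.2% higher. At 4-fold or more, 36 were higher and 52 were lower. The 10 lowest folds among symbols at or above the median larger average belonged to FLJ22184, H19, KIAA0831, IL8, MUC4, MYCL1, C7ORF13, LOC80054, H3F3AP1 and RGMA. H19 (ENSG00000130600), an imprinted long noncoding RNA, averaged 6.83 in the knockdown against 34.1 in the control, 4.49-fold lower. IL8 was 4.05-fold lower, the mucin gene MUC4 was 3.87-fold lower, and MYCL1, a MYC family gene that overlaps an antisense gene, was 3.84-fold lower. The 10 highest belonged to SNORA74B, PRNP, RPS4XP8, MIR641, SNORA66, SNORA26, C15ORF29, RPS2P4, SNORD3A and KIAA1731. PRNP (ENSG00000171867), which encodes the prion protein, averaged 34 against 3.33 and was 8.08-fold higher. Scaling the knockdown averages by 1.5 in either direction would leave 71.3% or 12.3% of the listed genes still past 2-fold higher, and 44.2% of the genes had a larger average under 2 times the smallest in the table.

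Pathway and cell type lists had few listed members in K562, and these were nearly all lower in the knockdown. Over all such lists, 32 distinct genes were listed, of which 2 were higher and 30, ADAR among them, were lower. In HepG2 the corresponding numbers were 149, 112 and 37. Among all listed protein-coding genes, 29.3% were higher in K562 and 55.5% in HepG2. The 2 higher genes of these lists in K562 were MBNL3 and EIF2C4. The 4 listed inflammatory genes, IL8, CSF1, CXCL16 and TRAF1, were lower, the last by 2.04-fold. The myeloid genes CSF3R, FCGR2A and ITGAM, which encode the receptor of granulocyte colony-stimulating factor, an Fc receptor and an integrin subunit, were 2.87-fold, 2.44-fold and 2.36-fold lower. The metallothionein genes MT2A and MT1H were 2.49-fold and 2.47-fold lower and the heat shock gene HSPA6 was 2.47-fold lower. LDHA, lactate dehydrogenase A, averaged 1364 against 3112 and was 2.28-fold lower, and NDRG1, a hypoxia-induced gene, was 2.35-fold lower. CCND1, which encodes cyclin D1, averaged 4 against 23 and was 4.80-fold lower. LOXL2, a lysyl oxidase of the matrix, was 3.04-fold lower, and ITGA2B, an integrin of the megakaryocyte lineage, was 2.40-fold lower. No erythroid gene of the list was in the K562 table. With fewer than 5 listed members each, these lists were given no percentile.

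Transcripts other than protein-coding genes made up more of the K562 table. Protein-coding genes were 63.8% of the HepG2 genes and 43.5% of the K562 genes, by Ensembl identifier in GENCODE release 29. Among protein-coding genes, 499 were higher and 400 lower in HepG2, and 120 were higher and 290 lower in K562. Among pseudogenes, 114 were higher and 104 lower in HepG2, and 141 were higher and 129 lower in K562. Of 47 listed K562 symbols that begin like ribosomal proteins, 44 were pseudogenes and 1, RPS6KA3, encodes a ribosomal S6 kinase; 33 were higher and 14 lower, with a median log2 fold of 1.17 at percentile 100. Without RPS6KA3 these were 33 and 13. RPS4XP8 was 6.47-fold higher and RPL12P35 was 22.1-fold lower. In HepG2 all 27 such genes were pseudogenes, 17 higher and 10 lower, at percentile 63.5, and RPL12P35 was 6.83-fold higher. Reads of such pseudogenes cannot be separated with certainty from those of their parent genes. Zinc-finger ZNF genes were higher in 16 of 21 cases in HepG2 (percentile 84.5) and in 13 of 23 cases in K562 (percentile 90.0).

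Genes listed in both tables mostly went in opposite directions. There were 94 matches by symbol or identifier, of which 30 went the same way (31.9%) and 64 went opposite ways. Of these, the symbols RN5S10, HIST2H3A and SNORD24 stand for different identifiers in the 2 tables; matched by identifier alone, 92 genes were shared, 29 in the same direction (31.5%). When directions were shuffled within each table, the same-direction share averaged 48.8%, and the central 95% of 10000 shuffles ran from 38.3% to 58.5%. Of the 64 genes, 40 were higher in HepG2 and lower in K562, and 24 were the reverse. Across these genes, which are not independent replicates, the log2 folds had a Pearson r of -0.36 and a Spearman rho of -0.33, and r was -0.39 without the 2 genes farthest from the median in HepG2. IL8 was 81.3-fold higher in HepG2 and 4.05-fold lower in K562. INHBE, an inhibin subunit gene induced by the stress response, averaged 675 against 32.5 in HepG2 and 52.2 against 170 in K562. STC2 was 19.2-fold higher in HepG2 and 2.60-fold lower in K562, and SERPINE2, a protease inhibitor, was 3.28-fold higher and 2.67-fold lower. REP15 and SLC2A13 were lower in HepG2 and higher in K562.

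Among genes with a symbol in the tables, ranked by the smaller of the 2 folds, those in the same direction in both lines were led by FAM133A, SNORD3A, CD83, PRTFDC1, NBEAL1, PLCB2 and FIG4, leaving out RN5S10. ADAR ranked 14 in this order, and some genes without a symbol in the tables had larger folds. FAM133A averaged 2 against 35 in HepG2 and 4 against 28 in K562, which was 12-fold and 5.80-fold lower. CD83, a surface glycoprotein of activated immune cells, was 3.45-fold lower in HepG2 and 2.40-fold lower in K562. PLCB2, a phospholipase C gene, was 3.19-fold and 2.20-fold lower. SNORD3A was 7.13-fold and 2.95-fold higher, and NBEAL1 was 2.48-fold and 2.26-fold higher. The smaller of each pair of averages was under 10 for several of these genes, and no replicate was available to set an error on them.

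**Figure D2:**
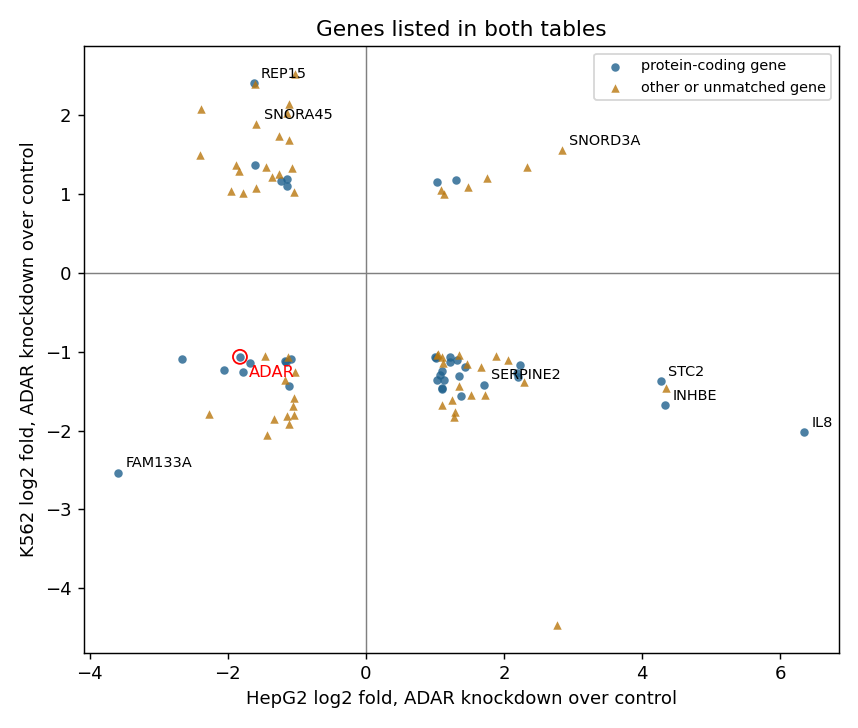
Log2 fold of the ADAR knockdown over the control in HepG2 (x axis) and in K562 (y axis) for the 94 genes listed in both tables by symbol or identifier, 1 point per match. Circles are protein-coding genes and triangles are other or unmatched genes; ADAR is ringed in red, and 64 of the points lie in the upper left and lower right areas, where the directions differ.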

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

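The tests of library depth, of single cultures, of noise in low averages, of surrounding genes, of control averages, of unequal directions and of shared pseudogene reads, and the look at small nuclear RNAs, were chosen after the results were seen; those of genes near the lowest averages, of small RNA recovery and of low averages among shared genes were set out before the values they measure were seen. With 1 sample per group, no difference between the cell lines was tested.

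Some genes stood in opposite directions in the 2 cell lines. IL8 had a log2 fold of 6.35 in HepG2 and -2.02 in K562, INHBE 4.33 and -1.68, STC2 4.27 and -1.38, SERPINE2 1.71 and -1.42, and HIST2H3A 1.52 and -1.55. The rows named HIST2H3A carry different identifiers in the 2 tables, so they are not the same locus. REP15 had -1.62 in HepG2 and 2.41 in K562, SNORA45 -1.58 and 1.89, and SLC2A13 -1.60 and 1.37. The small nucleolar and small nuclear RNAs had a median of -1.37 in HepG2 and 1.33 in K562.

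The higher inflammatory, stress-response and immediate early genes in the HepG2 knockdown were weighed first. One factor of library depth would move all genes one way, but 45.0% of the genes in the table were lower in the knockdown. This argues against depth as the only source of differences in the table. It cannot decide on depth for these members, since a factor acting beside other differences would also leave genes lower. Multiplying the knockdown averages by 1.5 still left 241 of 1016 genes lower. A part played by depth stays open, since the balance of directions rests on a scaling that cannot be checked. With the knockdown averages divided by 1.5, 39 of the 57 higher members stayed past 2-fold. Of the 57 members, 5.26% had a larger average under 2 times the smallest in the table (exact 95% interval 1.10% to 14.6%), against 27.6% of the whole table. Since the members were taken for being higher, they were also set beside the other 718 higher genes, of which 28.4% lay under that limit. On the control side 33.3% of the members lay under it (exact 95% interval 21.4% to 47.1%), against 62.0% of those genes. The members were thus less often at low averages than the other higher genes. Since the divisor of the averages differs between genes, an average does not give a read count, so noise of few reads is not excluded. In addition, 19 members have control averages under the limit, and no replicate sets an error on their folds. An effect of ADAR loss and a difference between single cultures, such as in their growth, cannot be told apart with 1 sample per condition. The biological explanation stays open as a hypothesis.

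The opposite directions of the list of small nucleolar and small nuclear RNAs were weighed next. Independent noise of low averages would place the medians inside the matched random sets. By the percentiles already reported for this list, they lay at 0.16 in HepG2 and 100 in K562. The list was fixed in advance, but these percentiles rest on the medians for which it was flagged. They are thus not a separate test of noise. A difference in small RNA recovery between libraries would move the 2 classes of small nucleolar RNAs alike. At least 85.7% of the H/ACA and of the box C/D RNAs went with the list in each cell line (84.6% with SNORD87 counted once). These classes made up 23 of the 28 listed RNAs in HepG2 and 20 of the 29 in K562. They thus largely set the direction they were compared with, so this comparison cannot decide on recovery. Recovery stays a candidate explanation, as does a difference in the RNAs themselves. Of the 4 small nuclear RNAs in HepG2, 3 went against the list, which a loss of all small RNAs alike would not give. They are too few to decide, and the 3 carry pseudogene names. RN7SKP70 among them lies inside CLK4 on the same strand, which was also higher, so its reads may come from CLK4. Host gene expression cannot be told apart, since of the 41 listed small RNAs with a position in the reference annotation, out of 57, only 2 lie inside another listed gene on the same strand, and both went with it. By identifier, 4 small RNAs were in both tables and 3 of them went opposite ways, SNORD3A being the exception.

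The mostly opposite directions of shared genes were weighed last. The same-direction share of 31.9% lay below the 38.3% to 58.5% given by shuffled directions, which argues against the unequal balance of the tables as the cause. Among 38 shared protein-coding genes the share was 31.6%, at the lower edge of the shuffled range of 31.6% to 63.2%, and among 28 genes at or above the median larger average in both tables it was 35.7%, inside a range of 28.6% to 67.9%. Falling inside the range was the outcome set out for low averages as the cause, but both ranges also hold the 31.9% of all 94 genes, a criterion added after that result was seen, so with this few genes neither pseudogene reads nor low averages can be excluded or shown. A true difference between the cell lines was not tested.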

How the results depend on the processing

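The protein-coding, symbol, scaling, member and small nucleolar alternatives were chosen after seeing the data; the others were planned. Of 159 alternative values under settings that could move at least some values, 125 were counted as unchanged. On the other side of 50% higher were 3 of them: hypoxia genes in HepG2 at 3-fold (33.3%), solute carriers in HepG2 above the lower quartile (58.8%) and protein-coding ZNF genes in K562 (47.4%). The 125 overstate stability, because some lists kept all members. With protein-coding genes alone, the HepG2 inflammatory, stress-response and immediate early lists kept their 22, 20 and 19. By construction, stricter thresholds and subsets hold fewer genes. At 3-fold, 471 genes were left in HepG2 (51.0% higher) and 210 in K562, and 9 in both tables (22.2% in the same direction); at 4-fold, 241 (52.3% higher) and 88. Protein-coding genes alone numbered 899, 410 and 38 shared, and were 29.3% higher in K562; genes with a symbol numbered 446 in K562 (33.0% higher) and 48 shared. With a larger average at or above the lower quartile, 54 were shared. Multiplying the knockdown averages by 1.5, a shift of 0.58 on the log2 scale, left 76.3% higher in HepG2 and reversed K562, with 505 genes left and 71.3% higher. Dividing by 1.5 reversed HepG2, with 883 genes left and 28.2% higher, and left 12.3% higher in K562. These reversals follow from the construction, since genes drop out on 1 side only; no gene still past 2-fold had another direction.

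For lists at 3-fold in HepG2, the share of members higher was 100% for the integrated stress response, epithelial, adhesion and cholesterol lists. These had 13, 3, 3 and 2 members left, those of the cholesterol list being ABCG1 and ACSL1. The share was 0% for drug metabolism, with 2 members left. In K562 it was 25% for ZNF genes, 84.6% for ribosomal protein names, and 100% for solute carriers and microRNA transcripts. With protein-coding genes alone it was 0% for the HepG2 heat shock list, where 6 of 7 members remained. The member left out, TXNIP, encodes a protein, but its identifier was not given that type by the reference annotation. This move therefore reflects annotation. For ribosomal protein names in K562 it was 50%, 1 of the 2 being the kinase gene RPS6KA3. Few members remained in either list. The epithelial list moved to percentile 97.9 when random sets were not matched on expression. A floor of 10 removed no gene, and pseudocounts of 1 and 0.1 could not remove any, so these settings show nothing about stability. A p or q threshold and each technical replicate alone were not run, because no p-value and no replicate value was used here. No paired analysis was possible within a cell line, because the groups share only 1 sample number and the columns are the authors' averages. Each fold is already within 1 cell line. A fit across the cell lines, which could use only the genes in both tables, was not run. Depth is unknown and limits low averages most.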

Other observations

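The gene groups in this part were put together after the values were seen, so their counts are descriptions. In the HepG2 knockdown, 5 of 12 ligands and receptors of the interleukin-6 family were listed, 4 higher and 1 lower: IL6, LIF, with 84.7 against 30.8, the shared receptor subunit IL6ST, with 134 against 52.2, and the oncostatin M receptor OSMR, with 591 against 235, were higher, and LIFR, with 54.8 against 153, was lower. Of 8 ligands of the EGF receptor, EREG averaged 530.1 against 60.2, EPGN 59.8 against 13 and AREGB 35 against 7, whereas HBEGF averaged 7.33 against 17.8. The aminoacyl-tRNA synthetase genes CARS, GARS and MARS were listed, all higher, at 3.19-fold, 2.70-fold and 2.19-fold. CARS overlaps the listed CARS1-AS1 and MARS the listed DDIT3, both on the opposite strand and both higher. None of these groups had a listed member in K562.

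Contractile and muscle genes were mostly lower in the HepG2 knockdown, with 8 of 9 listed genes lower and a median log2 fold of -1.62. CALD1, which encodes caldesmon, averaged 279 against 899, TAGLN 23.2 against 142, TNNC1 147 against 406 and ANKRD2 5.07 against 51.6, whereas MB, the myoglobin gene, averaged 102 against 35.5. All 6 listed HSP70, HSP40 and HSP110 chaperone genes were lower in HepG2, with a median of -1.80, and HSPA6 was lower in K562.

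Listed pseudogenes of mitochondrial genes were mostly lower in the knockdowns. In HepG2, 4 of 5 were lower, MTND4P24 being higher at 21 against 6.5, and in K562 all 7 were lower, with medians of -1.14 and -1.56. MTATP8P1 and MTATP6P1, counted separately, overlap on the same strand. MTATP6P1 averaged 408 against 1027 in HepG2 and 175 against 638 in K562. Nuclear copies share sequence with mitochondrial transcripts, and no gene encoded in the mitochondrial genome was in either table.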
